A study of Oryza sativa with 20 samples.

How the data were processed

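RNA was measured in lamina joint (LJ) and blade pieces of the first complete leaf of rice seedlings at 5 stages, in 2 libraries per tissue and stage, 20 libraries in 10 groups. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra kit, and strandedness is not given in the sources used here. The deposited values are FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library, and the submitters' processing notes name CASAVA 1.8, Trimmomatic 0.36, TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build IRGSP-1.0. Without stranded counting, reads of overlapping and antisense genes cannot be told apart, and near-identical copies of a gene can share reads.

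Each library listed the same 82632 features, 37829 rice gene IDs and 44803 other features with IDs starting EPlOSAG, which were left out of the tests. FPKM do not keep the number of reads: steps between low values gave relative sizes of 0.547 to 1.275, read as their most frequent spacing only, and no whole reads were recovered, so the depth per library is unknown and no counting intervals are given. The FPKM total over rice gene IDs ran from 860684 to 1079325 per library. Of the rice gene IDs, 3144 were listed at 0 in every library. No 2 libraries held identical values, and replicate libraries correlated across genes at 0.914 (blade S4) to 0.983 (LJ S1). In 4 of 10 groups, LJ and blade at S2 and S4, a library correlated better with one outside its group than the replicates did with each other. At S4 the libraries with the same number correlated across tissues at 0.953 and 0.938, against 0.928 between the LJ and 0.914 between the blade replicates.

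Genes at 1 FPKM or more in at least 2 libraries, 26403 in number, were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (the data.table package, version 1.17.8), with a mean-variance trend, 10 groups in 1 fit, 10 residual degrees of freedom and 4.09 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Differences on this scale understate the change of genes at low FPKM. Of the 17 comparisons fitted, 4 were main ones: LJ minus blade as the mean of 5 stages, S5 minus S1 in LJ, S5 minus S1 in blade, and the difference between these last changes. Errors of levels are SD over 2 libraries and errors of log2 differences are SE of the fit. Gene lists were tested with camera at a correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison.

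Tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per main comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes without overlap that have a symbol, and the extreme members and listed loci of each list, and 3 and 3 for single stages and neighbouring stages. Of 22 lists, 7 held loci. The parts of lists that rest on gene descriptions were void, since the tables used here do not pair descriptions with these IDs. The 40 pairs of symbol and ID in them came from background knowledge. The RefSeq gene annotation (assembly ASM3414082v1) carries an ID of the files' kind in 1 of 39387 entries, so pairs were checked only for the same chromosome and a position in gene order within 2% of it (median difference 0.51%). In this check 32 pairs passed and are named, 3 were contradicted and left out, and 5 whose symbol the annotation lacks stayed in their lists by ID and are not named. Of the 32 named genes, 31 passed the filter. Lists with at least 5 tested loci were tested as sets: primary wall cellulose synthases (5), brassinosteroid synthesis and signalling (12) and leaf angle genes (15), the last sharing members with the brassinosteroid and auxin lists. For the Calvin cycle (3), KNOX (3 of 4), secondary wall (4) and auxin response (4) lists only counts are given. Shares of plastid, mitochondrial and heat shock transcripts were not analysed here.

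The replicate numbers were checked for pairing. Within a stage, the difference between replicates 1 and 2 correlated between LJ and blade at 0.213 to 0.774 across genes, above 0.1 at each of the 5 stages, and across stages at −0.44 to 0.20 (median −0.0099). The numbers were therefore read as pairing LJ and blade within a stage, and a fit with these pairs as blocks was added after seeing the data. Other alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, upper quartile scaling, quantile normalization, an additive replicate number, only the groups compared, a 2-fold minimum and each library left out, where the remaining library of that group is assumed to vary like the other groups.

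The fit was tested on simulated data with 200 of 26403 genes changed. For the mean of 5 stages it recovered 74% of 2-fold and 96% of 4-fold changes, with 10.05% false calls. For LJ S5 minus S1 it recovered 5% and 59%, with 8.571% false calls, and for blade S5 minus S1 9% and 66%, with 6.25% false calls. These rates hold for 200 changed genes and noise independent between libraries. In the data, 11444, 17377 and 16563 genes were called in these comparisons, which loosens the adjusted cutoff, and same-numbered libraries deviated together. The rates therefore do not carry over to the data.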

Results

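Transcript levels were measured by RNA-seq in the first complete leaf of rice (Oryza sativa) seedlings, in the lamina joint (LJ), the hinge between leaf blade and leaf sheath whose bending sets the leaf angle, and in the blade. Both tissues were taken at 5 stages, named S1 to S5, that per the series design run from organ formation to the setting of the leaf angle. Each of the 10 groups of tissue and stage held 2 libraries, 20 in all. Tissue was collected on days 4, 5, 6, 7 and 9 after germination, and only the stage names are used here because the labels do not tie a day to a stage. The files gave FPKM for 37829 rice gene IDs, and 26403 of these reached 1 FPKM in at least 2 libraries and were tested. Between 18265 and 21695 genes reached 1 FPKM per library. The number of reads behind the values is unknown. Nothing in the labels says whether the 2 libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

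The stages lay along the leading axis of the principal components, which held 58.8% of the variance, and PC2 held 18.1%. LJ at S1 correlated best with blade at S1 (mean Pearson r across genes 0.899). LJ at S2 also correlated best with blade at S1 (mean r 0.925, against 0.874 with blade at S2), and LJ at S3 with blade at S2 (0.949, against 0.904 with blade at S3). LJ at S4 and S5 correlated best with blade of their own stage, at 0.916 and 0.932. The second blade library at S4 stood apart: 44.2% of its FPKM total lay in 50 genes and its median gene was at 0.849 FPKM, against 27.3% and 1.18 FPKM in the first. Genes are not independent replicates, and these correlations describe the libraries.

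**Figure D1:**
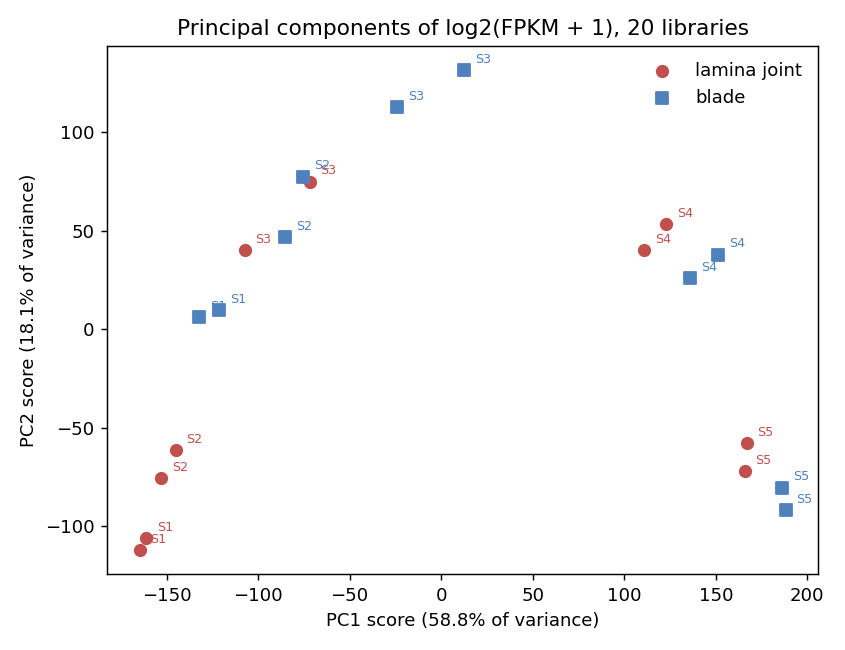
Principal components of log2(FPKM + 1) over the 26403 tested genes, with PC1 (58.8% of the variance) on the x axis and PC2 (18.1%) on the y axis. Each point is 1 of the 20 libraries, labelled with its stage; circles are LJ and squares are blade, and within each tissue the stages run from left (S1) to right (S5).

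The tissues were compared first over all stages together. DL (OS03G0215200), a YABBY transcription factor needed for the leaf midrib, stood higher in LJ at every stage, by 2.02 ± 0.13 (SE) on the log2(FPKM + 1) scale over the 5 stages (limma, adjusted p = 2.3e-07, 10 libraries per tissue), with no overlap between the libraries of the tissues at any stage, though at S5 the difference of 0.60 was not called (adjusted p = 0.28). Its mean level at S1 was 20.4 ± 3.79 FPKM in LJ and 0.637 ± 0.136 FPKM in blade (SD, n = 2). LG1 (OS04G0656500), the SBP-domain transcription factor required to form the lamina joint and ligule, was higher by 1.57 ± 0.12 (adjusted p = 7.2e-07), and LAZY1 (OS11G0490600), a gene of shoot gravitropism, by 1.44 ± 0.26 (adjusted p = 6.1e-04), which came from S4 and S5: at S1, S2 and S3 it stood at −0.34, −0.37 and −0.26, none of them called. The secondary wall cellulose synthases CESA7, CESA4 and CESA9 were lower in LJ, at −1.05 ± 0.21, −0.85 ± 0.23 and −0.85 ± 0.21, from negative values at S1 to S3. At S4 and S5 all 3 stood above 0, at 0.22, 0.51 and 0.10 at S5, and none was called.

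Of the 31 named genes tested, 16 were higher in LJ, 3 lower and 12 not called. Among the leaf angle genes, 10 of 15 were higher and 0 lower, with a median of 0.52, and 12 passed when adjusted over the list alone. This list rose as a set with camera (adjusted p = 0.048), with adjusted p = 0.18 with an estimated correlation and adjusted p = 0.17 when LJ and blade libraries of the same stage and number were paired. Brassinosteroid genes were higher in 7 of 12 cases (8 adjusted over the list alone), led by GSK2, a kinase that restrains brassinosteroid signalling, at 0.85 ± 0.15, the receptor BRI1 at 0.80 ± 0.17 and the transcription factor BZR1 at 0.67 ± 0.15. As a set they did not pass (camera adjusted p = 0.19, and adjusted p = 0.51 with an estimated correlation). The auxin-conjugating enzyme gene GH3-2 was higher by 0.71 ± 0.10 and GH3-1 by 0.36 ± 0.11. The mean of GH3-2 came from S4 and S5: at S1, S2 and S3 it stood at −0.01, 0.05 and −0.13, none of them called. GH3-1 was not called at any single stage. The primary wall cellulose synthases CESA6 (0.45 ± 0.13) and CESA5 (0.36 ± 0.12) were higher and the other 3 of 5 were not called (3 of 5 adjusted over the list alone, camera adjusted p = 0.74, adjusted p = 0.86 with an estimated correlation). These means join opposite directions: CESA5 was lower in LJ at S1 (−1.06, adjusted p = 0.016) and S2 (−0.91, adjusted p = 0.026), and CESA6 stood at −0.49 and −0.70 there, not called. With LJ and blade libraries paired, 2 of the leaf angle genes, 2 of the brassinosteroid genes and 2 of the 5 primary wall cellulose synthases were called lower. All 3 loci of the Calvin cycle list, matched by ID only, were lower in LJ, with a median of −2.44. These were entered as copies of the small Rubisco subunit gene, which can share reads, so they are not independent members of the pathway.

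All 3 tested KNOX homeobox genes, markers of the shoot meristem, were higher in LJ. OSH71 was higher by 0.98 ± 0.15, without overlap at any stage, OSH15 by 0.69 ± 0.13 and OSH1 by 0.56 ± 0.15. Their signal at S1 came unevenly from the 2 LJ libraries: OSH1 was at 6.82 ± 5.89 FPKM (SD, n = 2), OSH15 at 6.47 ± 4.88 FPKM and OSH6, which missed the filter, at 2.26 ± 2.00 FPKM. From S2 on, OSH1 had a mean of at most 0.221 FPKM in LJ, and it was listed at 0 in both blade libraries of each of these stages. At S2, S3 and S4, OSH71 had means of at most 0.560 FPKM in LJ and 0.0298 FPKM in blade, near the floor. Its mean difference came mainly from S1 (2.01 ± 0.32) and S5 (1.85 ± 0.32).

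In total 11444 genes were called, 7467 higher and 3977 lower in LJ, and 2003 of them changed at least 2-fold on this scale. With pairing the count was 15578, with 9866 higher and 5712 lower. The higher share was 65.2%, and 57.7% and 56.3% with upper quartile scaling and quantile normalization. The files do not pair IDs with names. Among the 1455 called genes whose libraries did not overlap at any stage, the unnamed IDs OS11G0150400 and OS08G0474100 had the highest values in LJ, at 4.01 ± 0.23 and 3.92 ± 0.14, and OS06G0316000 and OS12G0274750 the lowest, at −3.10 ± 0.23 and −3.06 ± 0.30. The calls of CESA5 and LIC were lost under both scalings and in 9 and 15 of the 20 fits with 1 library left out, with adjusted p up to 0.066 without blade S1 replicate 1 and 0.10 without blade S2 replicate 1.

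Of the named genes at S1, LJ was highest above blade in DL (3.70 ± 0.30), OSH15 (2.54 ± 0.30) and OSH1 (2.48 ± 0.34) and furthest below it in the U-type cyclin gene CYCU4;1 (OS10G0563900, −3.64 ± 0.27), CESA7 (−2.64 ± 0.47) and BU1, a bHLH gene that promotes lamina joint bending (OS06G0226500, −2.41 ± 0.23). CYCU4;1 was at 3.50 ± 0.652 FPKM in LJ and 54.9 ± 3.21 FPKM in blade (SD, n = 2). At S2, DL (3.04 ± 0.30) and SPL14, a regulator of plant architecture (0.90 ± 0.22), were higher in LJ, and CESA7 (−3.44 ± 0.47), CESA4 (−2.63 ± 0.51) and CESA9 (−2.52 ± 0.46) were lower.

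At S1, 4351 genes were called, 1564 higher and 2787 lower in LJ, and with LJ and blade libraries paired the count was 8734. It was 2018 without LJ S1 replicate 1, 2436 without LJ S1 replicate 2, 2564 without blade S1 replicate 1 and 2245 without blade S1 replicate 2. At S2, 6044 genes were called, 2770 higher and 3274 lower, 10439 with pairing and 614 when only these groups were fitted. The S2 count was 3201 without LJ S2 replicate 1 and 3175 without blade S2 replicate 1. The higher share was 35.9% at S1 and 45.8% at S2, and 57.5% and 60% with quantile normalization. With a pseudocount of 0.1, 757 genes were higher and 3188 lower at S1, and 2048 and 3662 at S2. At S2 the higher share was 51.3% with upper quartile scaling, and without LJ S2 replicate 2 the S2 count held 2372 higher and 2152 lower.

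At S3 the order of CYCU4;1 and BU1 was the opposite of that at S1. LJ was higher in BU1 (1.54 ± 0.23), DL (1.52 ± 0.30), LG1 (1.52 ± 0.27) and CYCU4;1 (1.46 ± 0.27). BU1 stood at 25.3 ± 2.83 FPKM in LJ and 8.15 ± 2.25 FPKM in blade (SD, n = 2), and CYCU4;1 at 132 ± 10.3 and 47.6 ± 8.29 FPKM. LJ was lower in the brassinosteroid synthesis genes DWARF4 (−1.78 ± 0.53) and D2 (−0.98 ± 0.31) and in CESA3 (−1.32 ± 0.41). At S3, 4471 genes were called, 2948 higher and 1523 lower, 9777 with pairing, 974 when only these groups were fitted, 1449 without LJ S3 replicate 2 and 1457 without blade S3 replicate 1. The higher share was 65.9%, and 55.2% and 54.8% under upper quartile scaling and quantile normalization.

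At S4 and S5, named genes that differed were higher in LJ. At S4, LAZY1 (2.51 ± 0.57), GH3-2 (2.24 ± 0.23) and LG1 (1.96 ± 0.27) led, and GH3-2 was at 4.83 ± 0.177 FPKM in LJ against 0.251 ± 0.282 FPKM in blade (SD, n = 2). At S5, LAZY1 differed by 5.64 ± 0.57 (50.4 ± 0.801 FPKM in LJ, 0.0300 ± 0.0424 in blade), LG1 by 3.16 ± 0.27 (21.2 ± 4.47 and 1.47 ± 0.169 FPKM) and OSH71 by 1.85 ± 0.32 (4.22 ± 1.43 and 0.420 ± 0.152 FPKM). The brassinosteroid receptor gene BRI1 (1.71 ± 0.38), BZR1 (1.33 ± 0.33) and GSK2 (1.29 ± 0.33) were higher at S5, the last not under quantile normalization (adjusted p = 0.091). All 5 primary wall cellulose synthases were higher in LJ at S5, from CESA5 at 1.35 ± 0.27 to CESA6 at 1.76 ± 0.28, but CESA1, CESA3 and CESA8 lost their calls under upper quartile scaling (adjusted p = 0.11, 0.068 and 0.050) and under quantile normalization (0.084, 0.056 and 0.071). CYCU4;1 was at 3.46 ± 0.179 FPKM in LJ and 0.307 ± 0.0807 in blade. Of the 31 named genes, 7 were called higher at S4 and 13 at S5, and limma called 0 of them lower at either stage.

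At S4, 1893 genes were called, 1768 higher and 125 lower, and at S5 2426, 2014 higher and 412 lower. With pairing the counts were 4833 and 5637. When only these groups were fitted, limma called 0 genes at S4, with 2881 at an unadjusted p under 0.05. Replicates differed most at S4, with an SD of their difference across genes of 0.793 in LJ and 0.876 in blade. It was 0.397 and 0.471 at S1, and 0.446 and 0.479 at S5. The shared estimate of spread can therefore be too small at S4 and too large at S1 and S5. The S4 count was 876 without blade S4 replicate 2 and 1125 without LJ S4 replicate 2, and the S5 count 1304 and 1512 without LJ S5 replicate 1 or 2 and 1305 and 1529 without blade S5 replicate 1 or 2. The higher share was 93.4% at S4 and 83.0% at S5, and 68.2% and 61.8% with quantile normalization. With upper quartile scaling the S4 share was 83.1%, and the median over all genes at S4 moved from 0.23 to 0.06, and to −0.06 with quantile normalization.

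**Figure D2:**
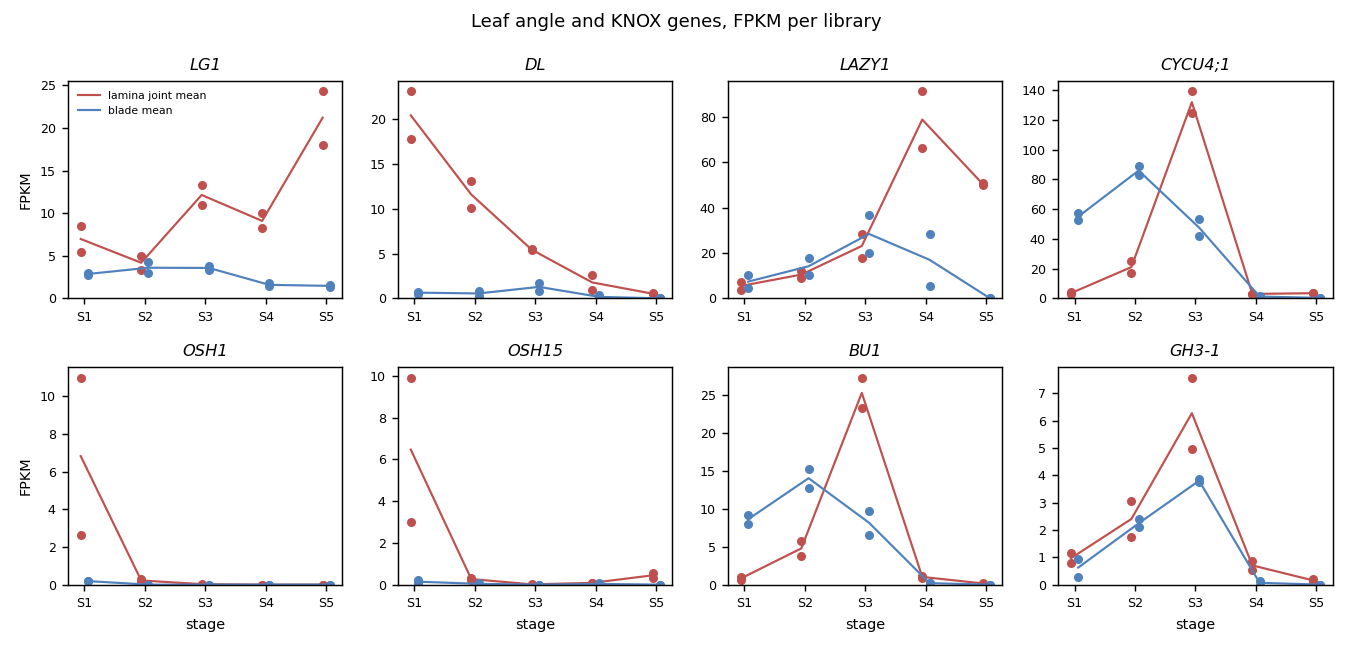
Expression of 8 leaf angle, KNOX and hormone response genes over the stages S1 to S5 (x axis), in FPKM on a linear y axis that starts at 0. Points are the 2 libraries of each group and lines join their means, red for LJ and blue for blade; LAZY1 ends at 50.4 FPKM in LJ and 0.0300 FPKM in blade, and the signal of OSH1 in LJ at S1 rests mainly on 1 library.

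The change from S1 to S5 was compared within each tissue. In LJ, the auxin response repressor gene IAA1 rose by 3.50 ± 0.46 (12.2 ± 1.92 to 147 ± 7.21 FPKM, SD, n = 2; limma adjusted p = 1.2e-05), LAZY1 by 3.05 ± 0.57, the brassinosteroid synthesis gene DWARF4 by 2.31 ± 0.53 and the auxin response factor gene ARF19 by 2.05 ± 0.37. LG1 rose by 1.49 ± 0.27, GH3-2 by 1.55 ± 0.23, CESA3 by 1.93 ± 0.41 and CESA8 by 1.77 ± 0.39. DL fell by 3.81 ± 0.30 (20.4 ± 3.79 to 0.521 ± 0.0812 FPKM, adjusted p = 8.1e-08), and OSH1 (−2.73 ± 0.34), OSH15 (−2.20 ± 0.30), SPL14 (−1.92 ± 0.22), GSK2 (−1.70 ± 0.33) and LIC, a zinc finger protein that opposes BZR1 (−1.24 ± 0.32), fell too. Falls were also called for CESA4 (−1.36 ± 0.51), CESA7 (−1.19 ± 0.47), BZR1 (−1.08 ± 0.33), GH3-1 (−0.76 ± 0.24) and BU1 (−0.64 ± 0.23).

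Of the 31 named genes, 8 rose, 11 fell and 12 were not called in LJ. Auxin response genes rose in 3 of 4 cases and fell in 1, with all 4 passing adjusted over the list alone. Brassinosteroid genes rose in 2 of 12 cases and fell in 5 (7 adjusted over the list alone, camera adjusted p = 0.28, adjusted p = 0.53 with an estimated correlation), and leaf angle genes rose in 4 of 15 and fell in 7 (11 adjusted over the list alone, camera adjusted p = 0.28, adjusted p = 0.53 with an estimated correlation). Primary wall cellulose synthases rose in 2 of 5 cases and fell in 0 (2 adjusted over the list alone, camera adjusted p = 0.35, adjusted p = 0.61 with an estimated correlation). Of 4 secondary wall genes, 2 fell, and 2 of 3 KNOX genes fell. The 3 Calvin cycle loci rose, with a median of 4.91. In all, 17377 genes were called, 9149 higher and 8228 lower at S5, and these were 8716 and 8713 with upper quartile scaling and 8304 and 9306 with quantile normalization. The falls of CESA7 (adjusted p up to 0.17 without LJ S5 replicate 1), CESA4 (0.18, the same library), BU1 (0.16 without LJ S1 replicate 2), GH3-1 (0.097 without LJ S1 replicate 1) and BZR1 (0.068 without LJ S1 replicate 1) lost their calls with 1 library left out, and that of CESA7 also under upper quartile scaling (adjusted p = 0.056).

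Between neighbouring stages of LJ, from S1 to S2, CYCU4;1 (2.27 ± 0.27) and BU1 (1.66 ± 0.23) rose, and OSH1 (−2.44 ± 0.34), OSH15 (−2.39 ± 0.30) and OSH71 (−1.75 ± 0.32) fell. From S2 to S3, CESA7 (4.04 ± 0.47), CESA4 (3.37 ± 0.51) and BC1, a COBRA-like gene of secondary walls (2.82 ± 0.49), rose, CYCU4;1 (2.62 ± 0.27) and BU1 rose again, and DL (−0.96 ± 0.30) and SPL14 (−0.95 ± 0.22) fell. CESA7 went from 2.54 ± 0.693 to 62.7 ± 38.2 FPKM (SD, n = 2). From S3 to S4, DWARF4 (2.54 ± 0.53), GH3-2 (2.17 ± 0.23) and LAZY1 (1.74 ± 0.57) rose, and CYCU4;1 (−5.06 ± 0.27), BU1 (−3.70 ± 0.23) and GH3-1 (−2.08 ± 0.24) fell. From S4 to S5, OSH71 (1.74 ± 0.32), LG1 (1.13 ± 0.27) and SPL14 (0.63 ± 0.22) rose, and CESA7 (−4.87 ± 0.47), CESA4 (−4.25 ± 0.51) and CESA9 (−3.08 ± 0.46) fell. The last rise of SPL14 lost its call under both scalings (adjusted p = 0.10 and 0.082).

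The 4 steps gave 437 genes (187 higher, 250 lower), 6260 (4003 and 2257), 11952 (4273 and 7679) and 7525 (5145 and 2380). When only the groups compared were fitted, limma called 0 genes for S1 to S2 and for S4 to S5, with 3177 and 9563 at an unadjusted p under 0.05, and 2087 and 7837 for the middle steps. The S1 to S2 count was 86 and 214 without LJ S1 replicate 1 or 2, and 828 and 124 without LJ S2 replicate 1 or 2. The S2 to S3 count was 4130 without LJ S2 replicate 1 and 2537 without LJ S3 replicate 1. The S4 to S5 count was 4551 without LJ S4 replicate 1 and 3139 and 4668 without LJ S5 replicate 1 or 2. The higher share was 63.9% for S2 to S3, 35.8% for S3 to S4 and 68.4% for S4 to S5, and with upper quartile scaling 50.7%, 47.3% and 50.4%. With quantile normalization these were 40.5%, 47.1% and 56.1%. For S1 to S2, 140 genes were higher and 33 lower with a pseudocount of 0.1, 132 and 76 with a filter at 5 FPKM, 238 and 234 with upper quartile scaling and 223 and 224 with quantile normalization.

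In blade, named genes mainly fell from S1 to S5. CYCU4;1 fell by 5.42 ± 0.27 (54.9 ± 3.21 to 0.307 ± 0.0807 FPKM, SD, n = 2; limma adjusted p = 1.7e-09), and CESA7 (−4.06 ± 0.47), CESA4 (−3.55 ± 0.51), BU1 (−3.26 ± 0.23) and LAZY1 (−2.93 ± 0.57) fell too. All 5 primary wall cellulose synthases fell, from −1.06 ± 0.41 for CESA3 to −2.61 ± 0.47 for CESA1, and all 4 secondary wall genes fell. GSK2 (−2.23 ± 0.33), the brassinosteroid synthesis gene BRD1 (−2.22 ± 0.56), BZR1 (−1.89 ± 0.33), SPL14 (−1.60 ± 0.22) and BRI1 (−1.44 ± 0.38) fell. ARF19 (2.56 ± 0.37), IAA1 (2.21 ± 0.46) and DWARF4 (1.46 ± 0.53) rose.

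Of the 31 named genes, 3 rose, 19 fell and 9 were not called in blade. The primary wall cellulose synthases fell as a set (5 of 5 adjusted over the list alone, camera adjusted p = 0.027), with adjusted p = 0.25 with an estimated correlation. Leaf angle genes fell in 10 of 15 cases and rose in 1 (12 adjusted over the list alone, camera adjusted p = 0.027), with adjusted p = 0.15 with an estimated correlation. Brassinosteroid genes fell in 6 of 12 cases and rose in 1 (7 adjusted over the list alone, camera adjusted p = 0.066, adjusted p = 0.25 with an estimated correlation). Auxin response genes rose in 2 of 4 cases and fell in 1, limma called 0 of 3 KNOX genes, and the 3 Calvin cycle loci rose, with a median of 3.12. In all, 16563 genes were called, 7176 higher and 9387 lower at S5, and these were 7461 and 9244 with upper quartile scaling and 8737 and 8161 with quantile normalization. The calls of LG1 (−0.65), BC1 (−1.25), GH3-1 (−0.67), CESA3 and DWARF4 were lost with 1 library left out, with adjusted p up to 0.17, 0.11, 0.27, 0.30 and 0.17, reached without blade S1 replicate 1 for GH3-1 and without blade S5 replicate 1 for the others. Those of BC1, CESA3 and LG1 were also lost under both scalings and that of GH3-1 under quantile normalization.

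Between neighbouring stages of blade, GH3-1 was the only named gene called from S1 to S2, with a rise of 1.03 ± 0.24 (limma adjusted p = 0.039). From S2 to S3, BC1 (1.92 ± 0.49), CESA4 (1.74 ± 0.51) and CESA3 (1.70 ± 0.41) rose and SPL14 fell by 1.19 ± 0.22. From S3 to S4, ARF19 rose by 1.47 ± 0.37, and CYCU4;1 (−4.49 ± 0.27), CESA5 (−3.39 ± 0.27) and CESA7 (−3.01 ± 0.47) fell. From S4 to S5, the brassinosteroid co-receptor gene BAK1 rose by 1.33 ± 0.28, and CESA4 (−4.19 ± 0.51), LAZY1 (−3.75 ± 0.57) and CESA7 (−3.59 ± 0.47) fell. CESA5 (0.86 ± 0.27) and SPL14 (0.69 ± 0.22) also rose at this last step, with both calls lost under both scalings. The call of CESA4 from S2 to S3 was lost too (adjusted p = 0.053 and 0.055).

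The 4 blade steps gave 734 genes (168 higher, 566 lower), 2769 (1355 and 1414), 8704 (2134 and 6570) and 8632 (6289 and 2343). When only the groups compared were fitted, limma called 0 genes for S1 to S2, S2 to S3 and S4 to S5, with 4615, 5184 and 8341 at an unadjusted p under 0.05, and 3968 for S3 to S4. The S1 to S2 count was 93 and 236 without blade S1 replicate 1 or 2, and 244 and 379 without blade S2 replicate 1 or 2. The S2 to S3 count was 754 without blade S2 replicate 2 and 947 without blade S3 replicate 1, and without blade S2 replicate 1 it held 1629 higher and 1090 lower. The S3 to S4 count was 5586 without blade S3 replicate 2, and the S4 to S5 count 4714 without blade S5 replicate 1. The higher share was 24.5% for S3 to S4 and 72.9% for S4 to S5, and 43.3% and 49.4% with upper quartile scaling and 51.9% and 55.7% with quantile normalization. For S3 to S4 the median over all genes was −0.25, and 0.11 with quantile normalization.

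**Figure D3:**
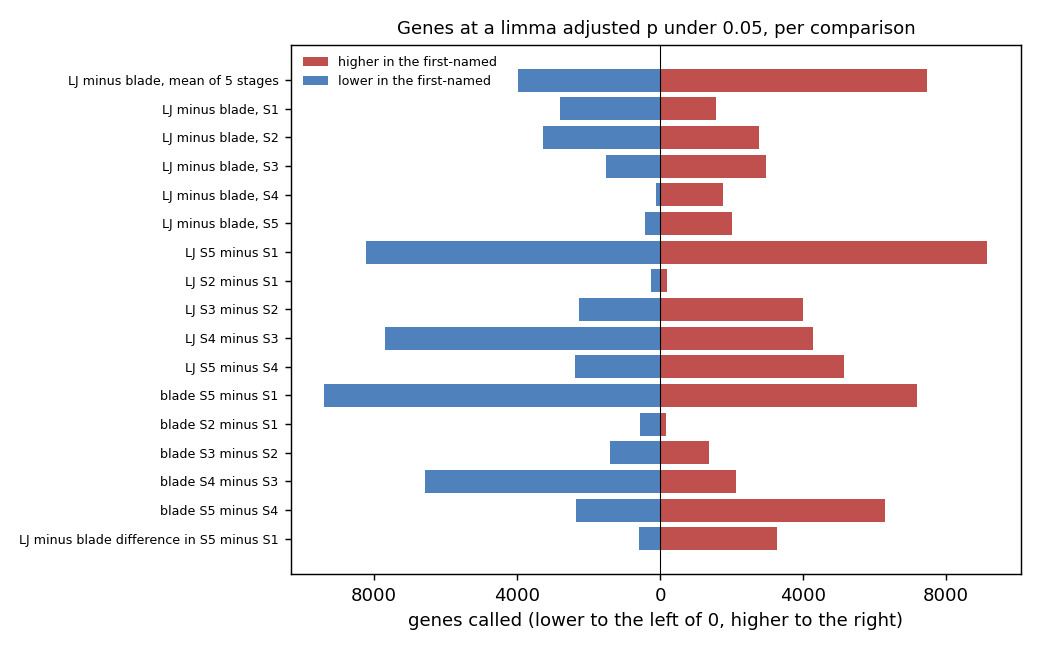
Genes called (limma, adjusted p under 0.05) in each of the 17 comparisons, with the number on the x axis and the comparison on the y axis. Red bars to the right of 0 are genes higher in the first-named group and blue bars to the left are genes lower in it; the counts run from 437 for LJ S2 minus S1 to 17377 for LJ S5 minus S1.

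The last comparison asked whether the change from S1 to S5 differed between the tissues. LAZY1 rose in LJ and fell in blade, a difference of 5.98 ± 0.81 (limma adjusted p = 1.9e-04, 8 libraries). CYCU4;1 changed by −0.01 ± 0.27 in LJ, which was not called, and fell by 5.42 in blade, a difference of 5.41 ± 0.38 (adjusted p = 1.0e-06). All 5 primary wall cellulose synthases differed in the same direction, at 3.93 ± 0.56 for CESA8, 3.03 ± 0.66 for CESA1, 2.99 ± 0.57 for CESA3, 2.40 ± 0.38 for CESA5 and 2.25 ± 0.40 for CESA6. At S1, LJ was lower than blade in CESA8 (−2.38), CESA3 (−1.46), CESA1 (−1.44) and CESA5 (−1.06), and CESA6 at −0.49 was not called. The call of CESA1 at S1 was lost under both scalings. At S5 the LJ minus blade values of these genes ran from 1.35 to 1.76, so the differences join both stages. BU1 differed by 2.62 ± 0.33, LG1 by 2.14 ± 0.38, CESA7 by 2.86 ± 0.66 and GH3-2 by 1.41 ± 0.33. BU1 and CESA7 fell in both tissues (−0.64 and −1.19 in LJ, −3.26 and −4.06 in blade). Their LJ minus blade values were −2.41 and −2.64 at S1, and 0.21 and 0.22 at S5, where neither was called. At S5 their means were at most 0.281 FPKM in either tissue, near the floor. DL, OSH1 and OSH15 had lower values, at −3.10 ± 0.43, −2.48 ± 0.48 and −2.01 ± 0.42.

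Of the 31 named genes, 11 had a more positive change in LJ, which can be a smaller fall, 3 a more negative one and 17 were not called. The primary wall cellulose synthases passed as a set (5 of 5 adjusted over the list alone, camera adjusted p = 3.4e-05), with adjusted p = 0.10 with an estimated correlation. Leaf angle genes differed upward in 5 of 15 cases and downward in 1 (6 adjusted over the list alone, camera adjusted p = 0.37, adjusted p = 0.50 with an estimated correlation), with a median of 0.53 that was −1.4e-04 under quantile normalization. Brassinosteroid genes differed upward in 2 of 12 cases (2 adjusted over the list alone, camera adjusted p = 0.50, adjusted p = 0.67 with an estimated correlation). In 1 of 4 secondary wall genes and 1 of 4 auxin response genes the difference was called, upward, and in 2 of 3 KNOX genes downward. With limma, 0 of the 3 Calvin cycle loci were called over all genes, and 3 passed adjusted over the list alone. With a pseudocount of 0.1, DL (−2.17, adjusted p = 0.15), OSH15 (−2.18, adjusted p = 0.075) and GH3-2 (3.21, adjusted p = 0.093) lost their calls, and GH3-2 did so also under quantile normalization (0.93, adjusted p = 0.070).

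In all, 3848 genes were called, 3258 higher and 590 lower, and 7198 with LJ and blade libraries paired. By the sign of the fitted changes, whether or not these were called in each tissue, 1410 of the 3848 had the same sign in both and the larger change in LJ, 1094 the same sign and the larger change in blade, and 1344 opposite signs. When only these groups were fitted the count was 6320, and without LJ S1 replicate 1 it was 2525. The higher share of 84.7% was 78.5% with upper quartile scaling and 50.3% with quantile normalization, where the median over all genes moved from 0.17 to −0.22.

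**Figure D4:**
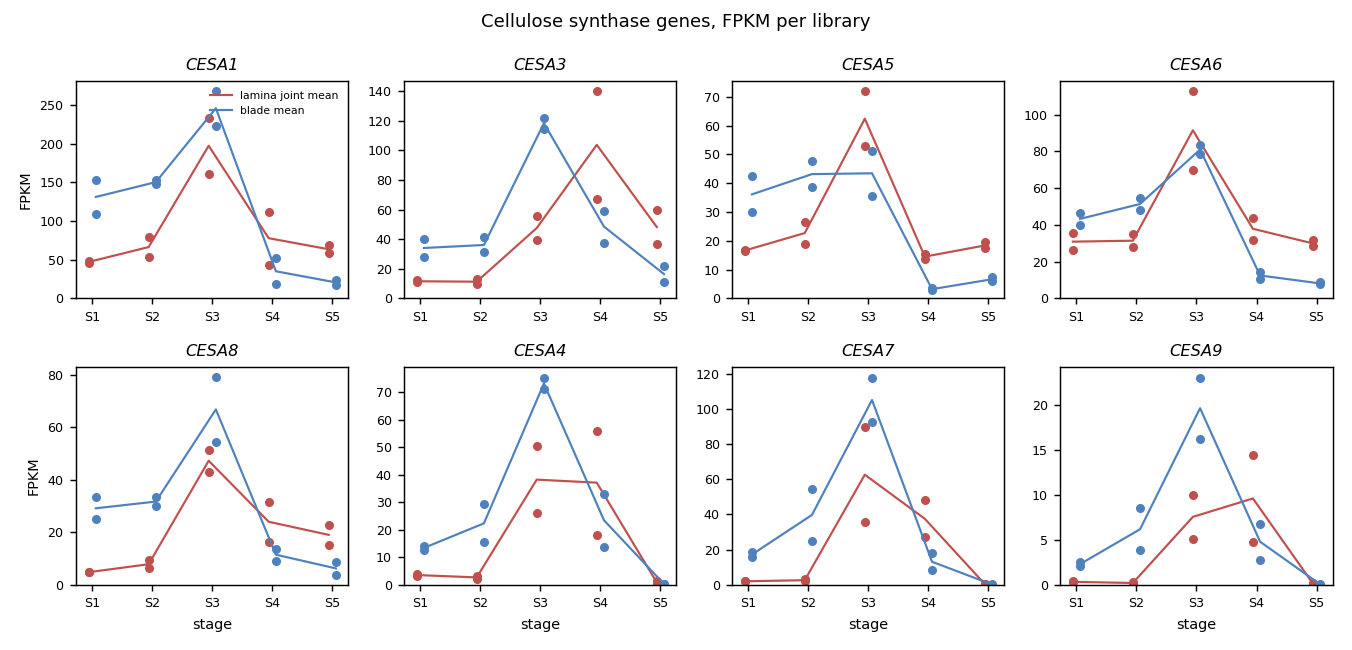
Expression of 5 primary wall (CESA1, CESA3, CESA5, CESA6, CESA8) and 3 secondary wall (CESA4, CESA7, CESA9) cellulose synthase genes over the stages S1 to S5 (x axis), in FPKM on a linear y axis that starts at 0. Points are the 2 libraries of each group and lines join their means, red for LJ and blue for blade; at S5 CESA1 was at 63.5 FPKM in LJ and 20.6 FPKM in blade.

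The genes called for the change from S1 to S5 overlapped between the tissues. Higher at S5 in both were 6426 genes, where independent lists of these sizes would share 2487, and lower in both were 6907, where 2925 would be shared. Another 412 genes were higher at S5 in LJ and lower in blade, LAZY1 and CESA8 among them, and 13 were lower in LJ and higher in blade. These comparisons share no library, although same-numbered LJ and blade libraries of a stage deviated together (r across genes 0.478 at S1 and 0.516 at S5).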

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

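Of the tests in this part, those of scaling factors and of blade tissue in the LJ pieces, of both explanations for the cellulose synthases, of harvest age at S4 and of the splits that part every pair were chosen after the results were seen.

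The change from S1 to S5 differed between LJ and blade for 3848 genes, by a test of the difference itself. Named genes with a higher change in LJ were LAZY1 (5.98), CYCU4;1 (5.41), CESA8 (3.93), CESA1 (3.03), CESA3 (2.99), CESA7 (2.86), BU1 (2.62), CESA5 (2.40), CESA6 (2.25), LG1 (2.14) and GH3-2 (1.41). Of these, BU1 and CESA7 fell in both tissues, less in LJ. Both ended near the floor, with S5 means of at most 0.281 FPKM in either tissue. Their smaller fall in LJ thus restates its lower level at S1. Named genes with a lower change were OSH15 (−2.01), OSH1 (−2.48) and DL (−3.10).

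LJ libraries at S2 and S3 correlated best with blade libraries of an earlier stage. Scaling between libraries, as factors of 0.25 to 4 on 1 group at a time, left the mean r higher with the earlier stage, by at least 0.039 at S2 and 0.0295 at S3. A factor is close to a constant shift on the log scale, which r hardly registers, so this outcome was largely fixed beforehand. It shows only that the measure depends little on scaling. The mean Spearman rho, which scaling cannot change, was 0.057 higher with the earlier stage at S2 and 0.0477 at S3, though this test nearly restates the pattern. Blade tissue carried into the LJ pieces would bring its abundant transcripts. Over the 1152 genes at 100 FPKM or more in all blade S1 and S2 libraries, the tenth lowest LJ level at S2 was 3.97% of the blade level, and with that share of blade S1 removed the lowest r of LJ S2 with blade S1 still lay 0.0109 above the highest with blade S2, which argues against it at S2. At S3 the tenth lowest was 52.2%, so a carried share there cannot be told apart from expression in LJ itself. With that share of blade S2 removed, the gap at S3 went from 0.0185 to −0.0497. Tissue carried at harvest would be of the same stage and would pull LJ toward blade of that stage. With same-stage blade removed, the gap was 0.0158 at S2 (0.0126 before) and 0.0209 at S3. Removing same-stage blade moves LJ away from that stage by construction. These gaps were therefore largely fixed beforehand and do not test the explanation. The rank and the bounds of the test of carried blade tissue were set after the levels were seen. A candidate explanation is that LJ runs behind blade in development: the LJ minus blade difference at S2 correlated at −0.725 across genes with the blade change from S1 to S3, a comparison of different libraries, though pattern and test come from the same data. The corresponding values at S3 and S4 were −0.521 and −0.30, and a lasting difference between the tissues stays open.

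The primary wall cellulose synthases changed more upward in LJ, with a median difference of 2.99 over the 5 loci, which joins lower LJ values at S1 with higher ones at S5. A few genes taking much of the FPKM total in blade would not leave the difference in place under quantile normalization. There the median was 2.81, and at least 2.43 with any 1 locus left out. The 50 highest genes held 17.6% and 15.3% of the total in blade at S1, and 24.9% and 27.1% at S5. Such shares can move the difference only a little, so this outcome was largely fixed beforehand. At S5 alone, CESA1, CESA3 and CESA8 lost their calls under quantile normalization. A delay of these loci in LJ by 1 stage could account for part of the S5 side and cannot be told apart from a lasting difference there. The median of LJ S5 minus blade S4 was 1.01, against 1.55 for LJ S5 minus blade S5. The former ran from 0.844 to 1.11 with 1 locus left out. Of the 5 loci, 4 lay above blade S4, from −0.02 to 2.21. The bound that would have excluded a delay was tightened after the median of 1.01 was seen. Over all tested genes, LJ at S5 correlated best with blade at S5 (mean r 0.932, against 0.823 with blade at S4). This argues against a delay of LJ as a whole by 1 stage at S5, but does not decide it for 5 loci.

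Same-numbered LJ and blade libraries of a stage deviated together. Scaling between libraries would remove this under quantile normalization, where the lowest of the 5 within-stage correlations was 0.224. Seedlings of 1 harvest being older or younger would tie the deviations to the change over neighbouring stages, and the median absolute r was 0.19, between the bounds set for the test, so this cannot be told apart from other shared handling, for which the labels give no batch. The stages went different ways. A harvest age shared by both tissues would give both values of a stage the same sign, which the median absolute r ignores. At S2 the values were −0.153 and 0.227, of opposite sign, which a shared harvest age would not give. At S3 they were 0.265 and 0.393, the last above the bound that would go with harvest age. At S4, where the pairs deviated most (r = 0.774), the larger absolute r was 0.015. This argues against harvest age at S4 and says nothing of the other stages.

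Other splits of the 4 libraries of each stage, 2 and 2, were fitted for the mean of 5 stages. Of 100 splits, the real one included, 1 called as many genes: the real split called 11444 and the highest other 3836. Since the numbers pair the libraries, 100 of the 512 splits that part every pair were fitted too, the real one included: 1 called as many genes, and the highest other called 7520, against a median of 3. The splits of the first kind also left pairs together. A random regrouping of these libraries therefore rarely gives such a count, and 1 in 100 is the lowest share that 100 splits can show. Chance differences between the plants harvested were not tested, since the libraries may be technical replicates. Nor do the splits show that each called gene differs.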

How the results depend on the processing

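No named gene call of the 4 main comparisons reversed under any alternative that tested it. The filter at 5 FPKM kept 15 of 19 calls for the mean of 5 stages and 15 of 19 for LJ S5 minus S1. It kept 21 of 22 for blade S5 minus S1 and 11 of 14 for the difference. The block within stage was not fitted for the changes within a tissue, nor only the groups compared for the mean. With 1 library left out, 24 of 380 such calls were lost for the mean of 5 stages, 14 of 76 for LJ S5 minus S1, 16 of 88 for blade S5 minus S1 and 0 of 112 for the difference, a 2-fold minimum ended 15 of 19, 2 of 19, 2 of 22 and 0 of 14 in the same order, and each other alternative ended at most 4 per comparison. Counts that moved by over 1.5 times were, with a 2-fold minimum, 2003 of 11444 for the mean of 5 stages; with a pseudocount of 0.1, 173 for LJ S2 minus S1 (main 437) and 159 for blade S2 minus S1 (main 734); and with a filter at 5 FPKM, 208 for LJ S2 minus S1. With the replicate block within stage, chosen after seeing the data, LJ minus blade gave 8734 at S1, 10439 at S2, 9777 at S3, 4833 at S4 and 5637 at S5, and 7198 for the difference in S5 minus S1; for the mean and the difference it ended 1 list call, that of the leaf angle genes at the mean (adjusted p = 0.17), and no named gene call. The additive replicate block moved no count by over 1.5 times (3 list tests past the threshold against 4). With only the groups compared, and fewer libraries behind the spread, LJ minus blade gave 614 at S2, 974 at S3 and 0 at S4, LJ steps 0, 2087, 7837 and 0, blade steps 0, 0, 3968 and 0, and the difference 6320; the counts of 0 from limma had 2881 genes at an unadjusted p under 0.05 at S4, 3177 and 9563 for the LJ steps and 4615, 5184 and 8341 for the blade steps. Smaller moves with only the groups compared went both ways. LJ minus blade rose to 5722 at S1 (main 4351) and fell to 1907 at S5 (main 2426), and LJ S5 minus S1 rose to 19554 (main 17377). Replicates differed more at S4 than at S1 or S5, so the shared spread does not suit all stages alike. With an estimated correlation 0 of 12 list tests passed, against 4. With 1 library left out the ranges were 9974 to 12915 for the mean of 5 stages, 2018 to 2564 at S1, 3175 to 4524 at S2, 1449 to 3896 at S3, 876 to 2769 at S4, 1304 to 1529 at S5, 14923 to 15184 for LJ S5 minus S1, 86 to 828, 2537 to 5832, 8105 to 10792 and 3139 to 6166 for the LJ steps, 13986 to 14574 for blade S5 minus S1, 93 to 379, 754 to 2719, 5586 to 8474 and 4714 to 9161 for the blade steps, 2525 to 3094 for the difference, and 2 (without blade S5 replicate 1) to 4 list tests. The cause of these moves was not tested. Depth is unknown, so its limit on low genes cannot be given.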

Other observations

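Some genes parted the tissues regardless of stage. In 31 genes all 10 LJ libraries lay above all 10 blade libraries, and in 3 all lay below. In 100 random splits of the libraries within stages the median number was 0 in either direction, with a maximum of 1 above and 0 below. These splits did not have to part the pairs of same-numbered libraries as the real one does, so their numbers may run low. None of the named genes was among the 31 or the 3. OS08G0474100, at 32.4 ± 8.83 FPKM in LJ at S3 and 0.0757 ± 0.107 FPKM in blade, was listed at 0 in blade at S4 and S5.

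The EPlOSAG features, outside the comparisons, were listed at 0 in all libraries in 43355 of 44803 cases, and 973 reached 1 FPKM in any library and 9 in all 20. Their FPKM total ran from 688534 to 13790607 per library, and the highest single value was 10131000 FPKM. The totals of rice gene IDs ran from 860684 to 1079325, and no comparison uses the EPlOSAG features.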
